A study of Mus musculus with 4 samples.

How the data were processed

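Nuclei were isolated from mouse heart and turned into libraries with the 10x Genomics Chromium single cell 5' kit, version 2, and sequenced on an Illumina NovaSeq instrument, per the labels. The deposited files hold raw UMI counts per gene and nucleus, made by the authors with Cell Ranger 7.1.0, per the file headers, with no normalisation. The processing notes also name Scanpy and the genome build GRCm39, without saying what Scanpy was used for. Every deposited barcode had at least 500 UMIs (501 in Q150X 3dpMI), so barcodes had been filtered before deposit, by settings that are not stated. The annotation at hand is of an earlier build, so genes are given by the symbols of the files and without coordinates. The matrix holds 33954 genes. Groups were taken from the labels of genotype and treatment, with 1 library in each of the 4 groups. The series describes the allele as made by genome editing to mimic a human stop-gained variant.

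Nuclei with fewer than 500 UMIs, fewer than 300 genes or more than 10% of UMIs from mitochondrial genes were removed, which took out 3, 29, 8 and 5 nuclei by genes and 7, 42, 0 and 1 by mitochondrial share in WT homeostasis, Q150X homeostasis, WT 3dpMI and Q150X 3dpMI. Doublets were called per library with Scrublet as implemented in Scanpy 1.11.5, and 258, 336, 1045 and 846 nuclei were removed. In Q150X homeostasis the automatic threshold marked only 0.0926% of nuclei, under the 0.5% set as the least for a library of over 5000 nuclei, so the highest scores were removed at 0.8% per 1000 nuclei instead, which came to 5.19%. The libraries kept 4123, 6142, 8104 and 7274 nuclei, with 5431923, 8393926, 25162405 and 26604001 UMIs. Median mitochondrial shares were 0.862%, 0.794%, 0.166% and 0.126%.

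The 4 libraries were clustered together without batch integration, on counts scaled to 10000 per nucleus and logged, 2000 variable genes (mitochondrial, ribosomal protein, Xist and Y-linked genes left out), 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1, with leidenalg 0.10.2 and igraph 0.11.9. The 35 clusters were named from marker lists of 17 classes. A cluster stayed unnamed where it rested on under 3 markers, where markers of another class outnumbered its own among its 10 leading genes, or where 3 times its median UMI count was still under that of its library and no marker of its class was among those genes. Clusters 10, 14, 20, 28, 30 and 32 stayed unnamed. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

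UMIs were summed per library and class and scaled to the total of the class (CPM). Each sum has an exact Poisson interval, each share of nuclei an exact binomial (Clopper-Pearson) interval, each ratio of sums an exact conditional binomial interval and each ratio of shares a log interval, all at 95% and all for counting error only. With 1 library per group no test was run and no p-value or count of changed genes is given. The Vegfa that free cardiomyocyte RNA would bring to a class is the CPM of the cardiomyocyte markers there over that in cardiomyocytes, times Vegfa in cardiomyocytes, an estimate added after seeing the data. Where a library had 0 UMIs, a fold was computed against a floor of 3 counts in that library.

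The genes named in the text follow a rule. For each genotype comparison and each of the classes cardiomyocyte, vascular endothelial, fibroblast, and macrophage or monocyte with at least 100 nuclei in both libraries, the 3 genes with the highest and the 3 with the lowest ratio were taken. They were ranked by the 95% bound nearest to 1, among genes with at least 50 UMIs over both libraries and a CPM in the class at least that of all other nuclei together in the library where the gene was higher. Mitochondrial, ribosomal protein, sex-linked, haemoglobin genes and gene models without a symbol were left out. The same rule was used for infarction in WT, with the Q150X value beside it. In each list, up to 2 members at each end with at least 50 UMIs were named. Vegfa was named throughout. A gene picked by this rule is not reported here.

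The 22 gene lists covered VEGF ligands and receptors, tip-cell and VEGF-responsive genes, capillary identity, arterial and Notch genes, junction and Tie genes, endothelial adhesion and activation, interferon response, hypoxia and glycolysis, cardiomyocyte stress and fetal genes, fatty acid oxidation, oxidative phosphorylation, sarcomere, calcium handling and conduction, extracellular matrix, activated fibroblasts, resting fibroblasts, chemokines and cytokines, resident macrophages, recruited monocytes and repair macrophages, proliferation, immediate early and heat shock genes, and cell death and p53 targets. A list is given as the median log2 ratio over members with at least 20 UMIs, with the 2.5 and 97.5 percentiles of 1000 Poisson resamplings and its percentile among 10000 random lists of the same size matched on expression in 20 bins. The filters, markers, naming rule for genes, lists, their least UMIs and the number of random lists were set before the data were examined. The number of resamplings and the bins were set later, while the code was written.

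Intervals were tested on simulated data. For ratios, over 16 pairs of class and comparison with 200 changed genes each, mean coverage was 95.7%, and the lowest for any fold size was 90.0%. For 136 list medians with 300 draws each, median coverage was 97.0% and the lowest 58.3%, with 19 lists under 90%. For those lists the text gives a wider range instead, between the medians of the members' lower and upper bounds, whose lowest coverage was 94.7%. This range was added after seeing the data, as was the choice to give no list medians of macrophages at or against homeostasis, where WT had under 100 such nuclei. An error in the resampling, which set members with 0 UMIs to another floor than the medians, was found and corrected before these values were made.

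Alternatives were a minimum of 1000 UMIs, a limit of 5% mitochondrial UMIs, no doublet removal, libraries clustered separately, resolution 2, totals without mitochondrial genes and the top 50 genes, centring on the median ratio, nuclei weighted equally, list members with at least 1 or 100 UMIs, and lists without their 2 members with most UMIs. Added after seeing the data were list medians within single clusters, endothelial-scoring unnamed clusters added to the class, the cardiomyocyte share with doublets and unnamed cardiomyocyte-scoring clusters added, and the ratio of macrophage to endothelial share ratios under other filters, doublet handling and clusters.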

Results

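Gene expression was measured by single-nucleus RNA sequencing in 4 libraries of nuclei isolated from mouse heart. The question was how a stop-gained variant of Vegfa, the gene of the endothelial growth factor VEGF-A, acts on the heart without injury and after myocardial infarction. Wild-type (WT) hearts and hearts carrying the edited allele, named Q150X, were sampled at homeostasis and 3 days after infarction (3dpMI), with 1 library in each group. The labels do not say whether hearts were pooled in a library. The sample titles mark the Q150X libraries "ho" and the others "wt", but the sources leave it unclear whether the Q150X animals carried the allele on both copies of Vegfa. The WT homeostasis library held 4390 nuclei and 5875965 unique molecular identifiers (UMIs), and the Q150X homeostasis library 6544 nuclei and 9283645 UMIs. The infarction libraries were deeper, with 9157 nuclei and 30413471 UMIs in WT and 8125 nuclei and 32657625 UMIs in Q150X. After filtering, 25643 of the 28216 nuclei were kept, with a median of 919 UMIs per nucleus in WT homeostasis, 968 in Q150X homeostasis, 1990.5 in WT 3dpMI and 2658 in Q150X 3dpMI. There were no replicate libraries, so no difference between groups has a test, and every interval below is a 95% interval that covers counting error only. Ratios of genes are ratios of CPM, the summed UMI counts of a class scaled to its total, Q150X over WT unless stated otherwise. Class names were given to clusters from marker genes and stand for nuclei that resemble the named cell type. Xist, the transcript that marks female cells, had 2 to 5 UMIs in each library, while the Y-linked gene Uty stood at 235, 205, 210 and 208 CPM in WT homeostasis, Q150X homeostasis, WT 3dpMI and Q150X 3dpMI.

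Vegfa (ENSMUSG00000023951) was counted in every library, at its highest level among the classes in cardiomyocyte-like nuclei. In these nuclei it stood at 718 (688 to 749) CPM in WT and 922 (888 to 957) in Q150X at homeostasis, a ratio of 1.28 (1.21 to 1.36). At 3dpMI the cardiomyocyte values were 597 (580 to 615) in WT and 703 (674 to 732) in Q150X, a ratio of 1.18 (1.12 to 1.24). Summed over all nuclei the order was the opposite, with 429 (412 to 447) in WT and 374 (361 to 387) in Q150X at homeostasis, and 217 (211 to 223) and 134 (130 to 139) at 3dpMI, beside the lower share of cardiomyocytes in the Q150X libraries. Fibroblast-like nuclei held 76.1 (WT) and 84.5 CPM (Q150X) at homeostasis, a ratio of 1.11 (0.877 to 1.42), and 95.6 and 99.1 at 3dpMI, a ratio of 1.04 (0.940 to 1.15). Free cardiomyocyte RNA, estimated from cardiomyocyte markers in the fibroblasts, would bring 22.3 and 44.1 CPM of Vegfa at homeostasis and 14.5 and 8.49 at 3dpMI. Vascular endothelial-like nuclei had 11 (WT) and 23 Vegfa UMIs (Q150X) at homeostasis, at 22.1 and 59.7 CPM, no more than the 23.6 and 86.5 expected from free RNA. At 3dpMI they stood at 32.7 and 28.4 CPM, with 41.0 and 15 expected, and macrophage- or monocyte-like nuclei at 14.6 and 17.6, with 19.7 and 8.54 expected, so no ratio is given for these classes. In cardiomyocytes the log2 ratio of Vegfa was 0.361 at homeostasis and 0.234 at 3dpMI, where the median over all genes was 0.174 and 0.053. No Vegfa ratio within single clusters is given. A count of transcripts carrying a stop codon does not check the genotype.

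**Figure D1:**
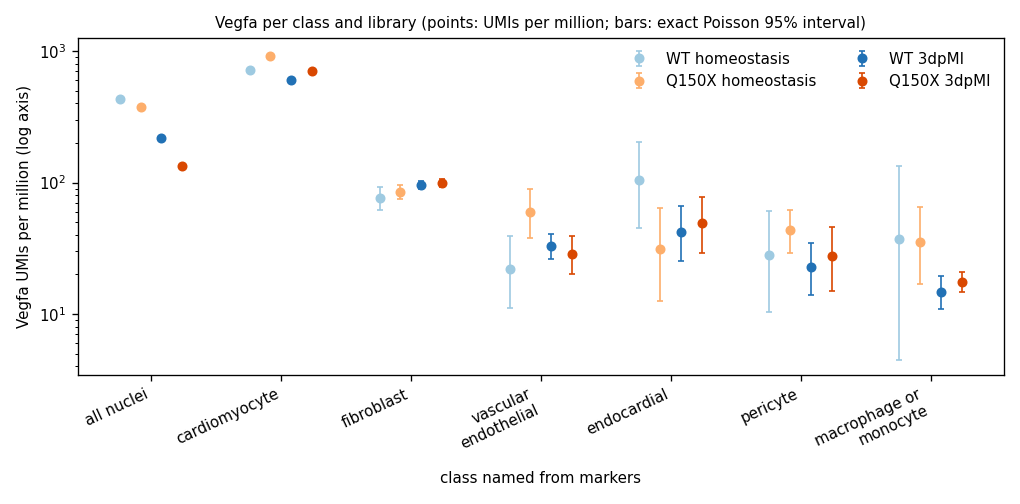
Vegfa CPM (log axis) in all nuclei and in each class (x axis), with points coloured by library and bars giving exact Poisson 95% intervals. Cardiomyocyte values run from 597 to 922 and are higher in Q150X than in WT at each time, whereas the values over all nuclei are lower in Q150X.

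The first comparison was of the make-up of the tissue. Cardiomyocyte-like nuclei took a smaller share in Q150X than in WT at both times. At homeostasis they made up 37.6% (36.1 to 39.1) of nuclei in WT and 13.8% (12.9 to 14.6) in Q150X, a ratio of 0.366 (0.340 to 0.394). At 3dpMI they made up 13.8% (13 to 14.5) and 5.07% (4.58 to 5.60), a ratio of 0.368 (0.329 to 0.413). Macrophage- or monocyte-like nuclei took a larger share in Q150X. Their share was 1.77% (1.39 to 2.22) in WT and 5.59% (5.02 to 6.19) in Q150X at homeostasis, a ratio of 3.15 (2.46 to 4.05), and 17.3% (16.5 to 18.2) and 34.8% (33.7 to 35.9) at 3dpMI, a ratio of 2.01 (1.90 to 2.13). Vascular endothelial-like nuclei made up 24.1% (23.2 to 25) in WT and 10.9% (10.2 to 11.7) in Q150X at 3dpMI, a ratio of 0.454 (0.421 to 0.490). At homeostasis the endothelial shares were 11.9% (10.9 to 12.9) and 8.32% (7.64 to 9.04), a ratio of 0.700 (0.623 to 0.787), a value that depends on the settings. It came to 0.178 when nuclei needed 1000 UMIs instead of 500 and 0.590 without doublet removal, but to 0.850 with at most 5% mitochondrial UMIs, 0.870 with libraries clustered separately, 0.880 at resolution 2 and 0.891 with the unnamed endothelial-scoring clusters added. Fibroblast-like nuclei made up 34.6% (33.1 to 36.1) in WT and 46.2% (45.0 to 47.5) in Q150X at homeostasis, a ratio of 1.34 (1.27 to 1.41), or 2.51 with the 1000-UMI minimum and 1.05 with libraries clustered separately. At 3dpMI they made up 21.7% (20.8 to 22.6) and 24.8% (23.8 to 25.8), a ratio of 1.14 (1.08 to 1.21). Among nuclei other than cardiomyocytes the fibroblast ratio was 0.967 (0.926 to 1.009) at homeostasis and 1.04 (0.981 to 1.10) at 3dpMI. Both intervals include 1, and this comparison was added after seeing the data. There the macrophage ratios, 2.28 and 1.83, stayed above 1 and the endothelial ratios, 0.506 and 0.412, below 1.

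The share ratios of pericytes and endocardial nuclei lay on opposite sides of 1 at the 2 times. Pericyte-like nuclei made up 5.55% (4.88 to 6.30) in WT and 12.4% (11.6 to 13.3) in Q150X at homeostasis, a ratio of 2.23 (1.94 to 2.58), but 6.22% (5.70 to 6.77) and 3.05% (2.67 to 3.47) at 3dpMI, a ratio of 0.491 (0.420 to 0.573). Endocardial-like nuclei had ratios of 1.70 (1.34 to 2.15) at homeostasis and 0.702 (0.567 to 0.867) at 3dpMI. Among nuclei other than cardiomyocytes their shares at homeostasis were 3.655% (2.963 to 4.454) in WT and 4.493% (3.951 to 5.086) in Q150X. These intervals overlap. At 3dpMI the shares among such nuclei were 3.091% (2.698 to 3.524) and 1.970% (1.655 to 2.326). Smooth muscle-like nuclei had ratios of 0.493 (0.339 to 0.717) and 0.338 (0.197 to 0.581), and lymphatic endothelial-like nuclei of 1.54 (1.05 to 2.25) and 1.03 (0.725 to 1.46). A further 2.40%, 6.27%, 8.87% and 11.2% of nuclei in WT homeostasis, Q150X homeostasis, WT 3dpMI and Q150X 3dpMI lay in clusters that could not be named. Of these, cluster 10, led by genes such as Selp and Vwf, and cluster 14, led by genes such as Kit and Angpt2, scored highest for endothelial markers. In the same library order, cluster 10 held 8.87%, 28.0%, 12.6% and 17.4% of all endothelial-scoring nuclei, and cluster 14 held 0.555%, 0.836%, 10.6% and 26.9%. A share depends on how well nuclei of every other class were recovered, and depth differed too, with median UMIs per cardiomyocyte nucleus of 1513, 3005, 6190 and 7857, and per vascular endothelial nucleus of 817, 653, 1085.5 and 1277.

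**Figure D2:**
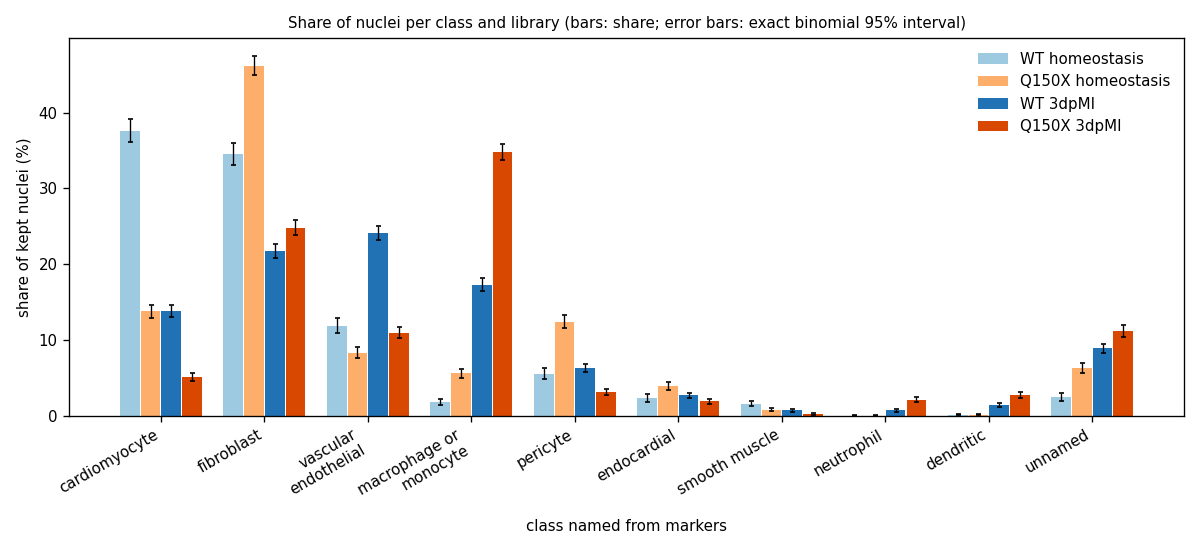
Share of kept nuclei (y axis, %) in each class (x axis), with 1 bar per library and exact binomial 95% intervals as error bars. In both pairs of libraries the cardiomyocyte bar is lower in Q150X (13.8% against 37.6%, and 5.07% against 13.8%) and the macrophage or monocyte bar is higher (5.59% against 1.77%, and 34.8% against 17.3%).

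The effect of the variant without injury was examined first within cardiomyocyte-like nuclei, 1551 in WT and 845 in Q150X. Genes of mitochondrial energy supply were higher in Q150X. In the list of nuclear-coded oxidative phosphorylation genes 25 of 26 measured members were higher, with a median log2 ratio of 0.66 (0.52 to 0.76), above all random lists matched on expression. Cox6a2, the muscle subunit of cytochrome c oxidase, had a ratio of 4.83 (3.39 to 7.05), and Ndufb9, a subunit of respiratory complex I, one of 2.99 (2.11 to 4.31). Of the fatty acid oxidation genes 25 of 26 were higher, with a median of 0.43 (0.34 to 0.51), above all random lists. Cpt2, which frees fatty acids from carnitine inside mitochondria, was at 2.28 (1.46 to 3.63) and Decr1, an enzyme of unsaturated fatty acid breakdown, at 2.08 (1.55 to 2.83), while Ppara, a transcription factor of this pathway, was at 0.894 (0.840 to 0.952). The median over all genes in this class was itself 0.17, and relative to it the medians were 0.49 for oxidative phosphorylation and 0.25 for fatty acid oxidation. Cluster 6 held 67.1% of the cardiomyocytes in WT and 32.2% in Q150X, and cluster 3 held 30.6% and 57.6%. Within clusters 3 and 6 alone the oxidative phosphorylation median was 0.51 and 0.78 and the fatty acid oxidation median 0.37 and 0.53. Abundant cardiomyocyte transcripts were also higher in endothelial nuclei of Q150X at homeostasis, with Mb at 6.09 and Actc1 at 4.63. Summed cardiomyocyte markers were at a ratio of 2.624 in endothelial nuclei and 1.025 in endocardial nuclei. How far free cardiomyocyte RNA bears on the medians in cardiomyocytes was not tested.

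Contractile genes differed less. The sarcomere list had a median of 0.24 (0.20 to 0.30), with 18 of 21 members higher, but 0.064 relative to the median of all genes. Actc1, cardiac alpha-actin, was at 2.95 (2.54 to 3.43) and Myl3, a ventricular myosin light chain, at 2.23 (1.95 to 2.55), while Ttn, the gene of titin, was at 0.823 (0.817 to 0.830). Calcium handling and conduction genes had a median of 0.078 (-0.008 to 0.12), with 11 of 19 higher, and -0.096 relative to all genes. Stress and fetal genes had a median of 0.33 (0.14 to 0.61), with 13 of 17 higher, and Nppb, the gene of B-type natriuretic peptide, was at 2.60 (1.72 to 4.01). Hypoxia and glycolysis genes had a median of 0.36 (0.27 to 0.48), with 18 of 21 higher, and 0.19 relative to all genes. The VEGF ligand and receptor list had 7 of 7 measured members higher and a median of 1.13 (0.67 to 1.47) in these nuclei, but 0.65 (0.36 to 1.05) within cluster 3, 0.59 (0.21 to 1.21) within cluster 6 and 0.58 without doublet removal. Within clusters 3 and 6 the medians were 0.36 and 0.73 for stress, 0.23 and 0.41 for hypoxia, 0.30 and 0.26 for sarcomere and 0.047 and -0.10 for calcium handling genes. Among the genes picked by the fixed rule, Sorbs2os, a transcript antisense to Sorbs2, was at 3.95 (3.05 to 5.18). On the low side were Sema3a, a guidance ligand of axons and vessels, at 0.150 (0.0716 to 0.283), and Fgf12, a modulator of sodium channels, at 0.184 (0.0793 to 0.377). Whether strand was used in counting is not given in the sources used here, so reads of Sorbs2os cannot be told from those of Sorbs2.

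Vascular endothelial-like nuclei of Q150X, 511 against 490 in WT, had lower levels of genes that mark the capillary state at homeostasis. Of the capillary identity genes 12 of 14 were lower, with a median log2 ratio of -0.41 (-0.60 to -0.26) at percentile 0.0200 of random lists. Fabp4, a fatty acid carrier of heart capillaries, was at 0.516 (0.447 to 0.594) and Btnl9 at 0.576 (0.456 to 0.725), while the water channel gene Aqp1 was at 1.6 (1.21 to 2.11). Arterial and Notch genes had a median of -0.18 (-0.50 to 0.087), with 5 of 12 higher and Efnb2, an arterial ephrin, at 0.588 (0.453 to 0.759). Tip-cell and VEGF-responsive genes had a median of -0.043 (-0.17 to 0.17), with 5 of 11 higher, and junction and Tie genes one of -0.038 (-0.22 to 0.082), with 4 of 10 higher, while the tip-cell median came to -0.28 at resolution 2 and the junction median to -0.33 with the 1000-UMI minimum. Among VEGF ligands and receptors the main receptor gene Kdr was at 0.768 (0.636 to 0.926) and the ligand gene Vegfc at 3.29 (2.32 to 4.74), and the list's median was -0.002, with a range of -0.15 to 0.59 from the bounds of its members. The highest ratios were those of 3 abundant cardiomyocyte transcripts, myoglobin (Mb, 6.09, 3.90 to 9.90), cardiac troponin I (Tnni3, 4.81, 2.94 to 8.20) and Actc1 (4.63, 3.21 to 6.82). In the same nuclei the summed cardiomyocyte markers were at 3145 CPM in WT and 8254 in Q150X. The lowest were Gphn, the gene of the scaffold protein gephyrin, at 0.284 (0.267 to 0.303), Lars2, the mitochondrial leucyl-tRNA synthetase, at 0.366 (0.315 to 0.424), and Eef1a1, a translation elongation factor with processed copies in the genome, at 0.386 (0.260 to 0.562). Cluster 1 held 93.5% of the class in WT and 88.9% in Q150X.

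Fibroblast-like nuclei, 1426 in WT and 2839 in Q150X, had higher levels of matrix genes in Q150X at homeostasis. Summed cardiomyocyte markers in these nuclei were at 2980 CPM in WT and 4209 in Q150X, so a gene abundant in cardiomyocytes can be higher here through free RNA. Of the extracellular matrix genes 18 of 24 were higher, with a median log2 ratio of 0.29 (0.21 to 0.37), above all random lists. Col1a1, a chain of type I collagen, was at 2.60 (2.04 to 3.35) and Mgp, an inhibitor of calcification, at 2.69 (2.13 to 3.44). Genes of activated fibroblasts had a median of 0.080 (-0.11 to 0.30), with 7 of 12 higher, and those of resting fibroblasts one of 0.24, with 9 of 14 higher and a range of -0.15 to 0.44 from the bounds of its members. In the proliferation list 7 of 9 measured members were lower, with a median of -0.59 (-1.64 to -0.039), but within cluster 0 alone the median was 0.090 (-0.35 to 0.46). Cluster 16, led by genes such as Diaph3 and Anln, held 3 WT and 2 Q150X nuclei at homeostasis, so the list's median may rest on few nuclei. Diaph3, a formin that nucleates actin, was at 0.232 (0.158 to 0.339), and came to 0.1245 with the 1000-UMI minimum, 0.535 with nuclei weighted equally and 0.753 with libraries clustered separately. The list's median came to -2.80 with the 1000-UMI minimum. The highest genes also included Atp5k, an ATP synthase subunit, at 4.12 (2.27 to 8.18) (or 9.99 with the 1000-UMI minimum), and Mcoln1, a lysosomal cation channel, at 5.71 (2.11 to 21.7), on 4 UMIs in WT and 56 in Q150X. Gphn was at 0.314 (0.304 to 0.325) and Lars2 at 0.404 (0.368 to 0.444), low as in endothelial nuclei. Cluster 0 held 91.8% of the class in WT and 92.7% in Q150X. Within clusters 0 and 18 alone the matrix median was 0.27 and 0.18 and the resting median 0.18 and -0.10.

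The effect of the variant after infarction was examined in the same classes, first in cardiomyocyte-like nuclei, 1116 in WT and 369 in Q150X at 3dpMI. Stress and fetal genes were higher in Q150X in all 19 measured members, with a median log2 ratio of 1.11 (1.01 to 1.23), above all random lists. Hspb1, a small heat shock protein, was at 2.85 (2.39 to 3.41) and Ccn2, a matricellular protein, at 2.71 (2.41 to 3.05), whereas Myh7, the fetal myosin heavy chain, was at 1.12 (1.03 to 1.23). Of the fatty acid oxidation genes 24 of 26 were lower, with a median of -0.46 (-0.53 to -0.37), below all random lists, in contrast to homeostasis. Ppargc1a, a coactivator of mitochondrial biogenesis, was at 0.531 (0.502 to 0.561), and Ucp3, a mitochondrial uncoupling protein, at 0.483 (0.351 to 0.653). Hypoxia and glycolysis genes were higher in 20 of 22 members, with a median of 0.48 (0.40 to 0.62) and the glucose transporter gene Slc2a1 at 2.15 (1.64 to 2.84). Cluster 13, led by genes such as Ankrd1 and Xirp2, held 69.4% of the cardiomyocytes in Q150X and 31.2% in WT, and cluster 3 held 22.2% and 52.9%. Within cluster 13 alone the stress median was 0.48 and the fatty acid oxidation median -0.15, and within cluster 3 they were 0.078 and -0.057. The hypoxia median was 0.54 within cluster 13 and 0.26 within cluster 3.

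Immediate early and heat shock genes were also higher in cardiomyocytes of Q150X at 3dpMI, in 18 of 20 members, with a median of 0.68 (0.51 to 0.92), or 0.23 (-0.14 to 0.69) within cluster 3 and 0.52 (0.25 to 0.69) within cluster 13. The survival gene Ier3 was at 3.51 (2.69 to 4.61) and the transcription factor gene Myc at 2.77 (1.90 to 4.06). Calcium handling and conduction genes were lower in 14 of 20 members, with a median of -0.22 and a range of -0.32 to -0.027 from the bounds of its members, but -0.054 (-0.11 to 0.014) within cluster 3 and -0.14 (-0.22 to -0.078) within cluster 13, and Kcnip2, a subunit of potassium channels, was at 0.492 (0.425 to 0.567). Oxidative phosphorylation genes had a median of -0.080 (-0.16 to -0.018) and sarcomere genes one of 0.15 (0.093 to 0.18), and within clusters 3 and 13 alone the oxidative phosphorylation median was 0.033 and 0.008, not below 0, and the sarcomere median 0.097 and 0.079. With libraries clustered separately the oxidative phosphorylation median came to 0.005. VEGF ligands and receptors had a median of -0.44 (-0.98 to -0.069), with 8 of 9 lower, but 0.098 within cluster 3 and -0.78 within cluster 13. Vegfa itself, at 1.18, was the member that was higher. The list includes the endothelial markers Flt1 and Kdr, and endothelial nuclei made up 24.1% in WT and 10.9% in Q150X. Free endothelial RNA in cardiomyocyte nuclei was not tested. Among the genes picked by the fixed rule, Thbs4, a thrombospondin of stressed muscle, was at 11.1 (7.5 to 16.7), Serpinb1a, an inhibitor of leukocyte proteases, at 7.30 (4.6 to 12), and the stress-induced gene Sprr1a at 6.39 (5.26 to 7.81). On the low side were Mylk4, a myosin kinase, at 0.287 (0.245 to 0.335), Ces1d, a lipid-cleaving carboxylesterase, at 0.263 (0.203 to 0.336), and Cfap61, a gene of motile cilia, at 0.223 (0.129 to 0.362), on 189 UMIs in WT and 18 in Q150X. With nuclei weighted equally Thbs4 came to 7.05.

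Vascular endothelial-like nuclei at 3dpMI, 1952 in WT and 795 in Q150X, again had lower capillary identity genes in Q150X. Of these genes 13 of 14 were lower, with a median log2 ratio of -0.43 (-0.51 to -0.31), below all random lists. Aqp1 was at 0.487 (0.411 to 0.576) and Tcf15, a transcription factor of heart capillaries, at 0.567 (0.404 to 0.783), while Fabp4 was at 1.20 (1.11 to 1.30). Kdr was at 0.729 (0.659 to 0.805), and 7 of 10 VEGF ligands and receptors were lower, with a median of -0.22 (-0.39 to -0.080). Proliferation genes were higher in 18 of 19 members, with a median of 1.05 (0.82 to 1.26) and the mitotic genes Aspm at 3.56 (2.04 to 6.38) and Kif11 at 3.05 (1.87 to 5.05). Tip-cell and VEGF-responsive genes had a median of 0.26 (0.068 to 0.33), with 9 of 15 higher and Plvap, a gene of fenestrated vessels, at 2.09 (1.47 to 2.97), but within cluster 1 alone their median was -0.13. The class leaves out the unnamed cluster 14, whose leading genes include the members Trp53i11, Igfbp3 and Angpt2 of this list. Cluster 14 held 10.6% of endothelial-scoring nuclei in WT and 26.9% in Q150X, so the list medians of the class do not cover such nuclei. Arterial and Notch genes had a median of 0.28 (0.15 to 0.40), with 11 of 14 higher, which turned to -1.08 when each library was clustered separately and was -0.12, 0.047 and 0.10 within clusters 1, 15 and 17. The proliferation median was 0.59, 0.41 and 0.60 within these clusters, and 4.05 with libraries clustered separately. Chemokine and cytokine genes had a median of 0.52 (0.28 to 0.93), adhesion and activation genes one of 0.25 (0.092 to 0.60) (0.45, -0.54 and 0.045 within clusters 1, 15 and 17) and junction and Tie genes one of -0.070 (-0.16 to 0.024). Cluster 1 held 69.9% of the class in WT and 52.3% in Q150X, and cluster 15 held 17.2% and 30.6%. The capillary median was -0.33 (-0.43 to -0.20) within cluster 1, -0.18 (-0.51 to 0.018) within cluster 15 and -0.18 (-0.36 to -0.002) within cluster 17.

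Genes of other cell types were among those picked by the fixed rule in these endothelial nuclei. The macrophage genes Spp1, at 2.93 (2.52 to 3.41), and Fcer1g, at 3.69 (2.58 to 5.33), were among the highest, with Ptchd1 at 4.26 (2.58 to 7.22), in libraries whose macrophage shares were 34.8% in Q150X and 17.3% in WT. These ratios depend on the settings, and came to 1.85 for Spp1 with libraries clustered separately, 2.34 for Fcer1g with at most 5% mitochondrial UMIs and 1.88 for Ptchd1 with the 1000-UMI minimum. The lowest were the muscle genes Ckm, at 0.225 (0.113 to 0.409), and Mb, at 0.317 (0.242 to 0.409), and Cyp4b1, a fatty acid hydroxylase, at 0.311 (0.226 to 0.420). Summed cardiomyocyte markers in these nuclei were at 5648 CPM in WT and 1583 in Q150X.

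Fibroblast-like nuclei at 3dpMI, 1758 in WT and 1803 in Q150X, had higher levels of genes of activated fibroblasts in Q150X. Of these genes 17 of 18 were higher, with a median log2 ratio of 0.57 (0.49 to 0.65), above all random lists. Comp, a cartilage matrix protein, was at 3.35 (2.12 to 5.51) and Cilp, a matrix protein of scars, at 2.89 (2.55 to 3.28), whereas Acta2, smooth muscle actin, was at 0.866 (0.756 to 0.994). Resting fibroblast genes were lower in 12 of 13 members, with a median of -0.29 and a range of -0.51 to -0.17 from the bounds of its members. Hsd11b1, which activates glucocorticoids, was at 0.322 (0.270 to 0.382) and the ferritin receptor gene Scara5 at 0.450 (0.408 to 0.496). Matrix genes had a median of 0.19 (0.16 to 0.22), with 21 of 25 higher and Col5a2, a chain of type V collagen, at 1.41 (1.38 to 1.44). Proliferation genes had a median of 0.087, with 17 of 20 higher and a range of -0.058 to 0.35 from the bounds of its members, but -0.33, 0.49 and -0.052 within clusters 4, 7 and 16 alone. The highest single genes were Adamts16, a secreted metalloprotease, at 4.34 (3.42 to 5.57) (or 8.57 with nuclei weighted equally), and the growth factor genes Nrg1 at 4.16 (3.58 to 4.85) and Ptn at 3.55 (3.15 to 4.0). The lowest were Chl1, a cell adhesion gene, at 0.184 (0.110 to 0.297), Prr16 at 0.228 (0.162 to 0.315) and Nkain2 at 0.313 (0.281 to 0.347). Cluster 4, led by genes such as Kif26b and Postn, held 57.0% of the fibroblasts in Q150X and 32.9% in WT, and cluster 7 held 18.6% and 35.4%. Within clusters 0, 4, 7 and 16 alone the activated median was 0.045, 0.29, 0.54 and 0.30, the matrix median 0.35, -0.023, 0.33 and 0.008, and the resting median -0.069, 0.053, -0.054 and 0.042, each resting median with an interval that includes 0.

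Macrophage- or monocyte-like nuclei at 3dpMI, 1403 in WT and 2532 in Q150X, had higher levels of genes of recruited monocytes and repair macrophages in Q150X. These were higher in all 19 measured members, with a median log2 ratio of 0.65 (0.55 to 0.77), above all random lists. Spp1, the gene of osteopontin, was at 2.12 (1.98 to 2.28) and Ms4a4c at 2.12 (1.75 to 2.58). Interferon response genes were higher in 21 of 23 members, with a median of 0.35 (0.23 to 0.46) and the ubiquitin-like modifier gene Isg15 at 2.02 (1.32 to 3.16). Hypoxia and glycolysis genes were higher in 22 of 23 members, with a median of 0.27 (0.18 to 0.35). Resident macrophage genes were lower in 10 of 14 members, with a median of -0.19 (-0.31 to -0.14) and Lyve1, a hyaluronan receptor of resident cells, at 0.423 (0.330 to 0.541), while Mertk, a receptor for dead cells, was at 1.16 (1.11 to 1.21). Proliferation genes were lower in 16 of 20 members, with a median of -0.19 (-0.29 to -0.093). Il1r2, a decoy receptor of interleukin 1 that also leads the neutrophil-like cluster, was at 4.11 (2.75 to 6.37), H2-Ab1, an antigen presentation gene, at 2.76 (2.0 to 3.88), and Adra1a, an adrenergic receptor gene, at 3.22 (2.33 to 4.54), and with libraries clustered separately H2-Ab1 came to 4.48 and Adra1a to 1.48. The scavenger receptor gene Marco was at 0.111 (0.0600 to 0.192), the transporter gene Slc13a3 at 0.161 (0.116 to 0.219) and Cmah, an enzyme of sialic acid, at 0.257 (0.196 to 0.336). Cluster 2, led by genes such as Gpnmb and Arg1, held 48.5% of the class in Q150X and 30.3% in WT, and cluster 11 held 14.6% and 27.9%. Within clusters 2, 8, 9, 11 and 22 alone the recruited median was 0.52, 0.095, 0.99, 0.60 and 0.39. The resident median within them was 0.021, 0.85, -0.46, 0.051 and 0.25, below 0 in cluster 9 only, and the proliferation median 0.018, -0.033, 0.24, 0.11 and -1.35. The interferon median within them was 0.16, 0.30, 0.024, 0.41 and -0.24, and the hypoxia median 0.17, 0.023, -0.012, 0.18 and 0.23.

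**Figure D3:**
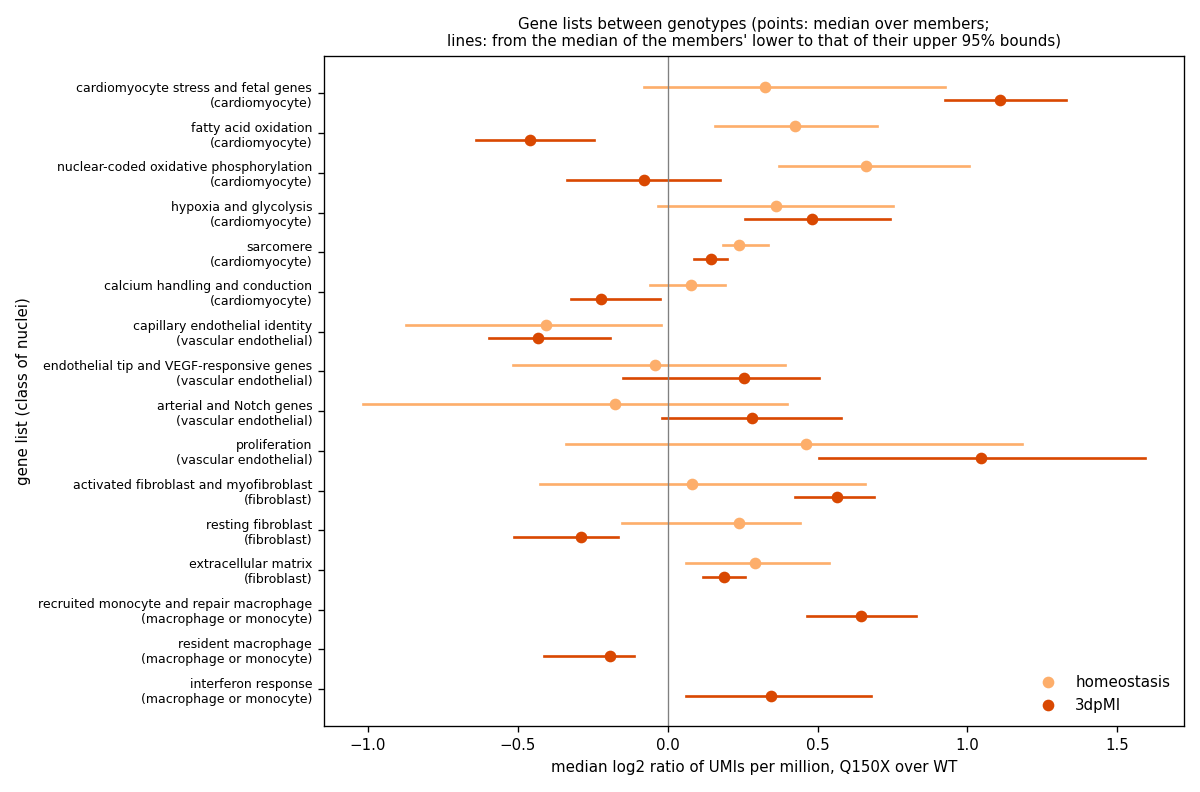
Median log2 ratio of CPM, Q150X over WT (x axis), for pairs of gene list and class (y axis) at homeostasis and at 3dpMI. Points are medians over list members and lines run between the medians of the members' lower and upper 95% bounds, and the points for fatty acid oxidation lie at 0.43 and -0.46.

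**Figure D4:**
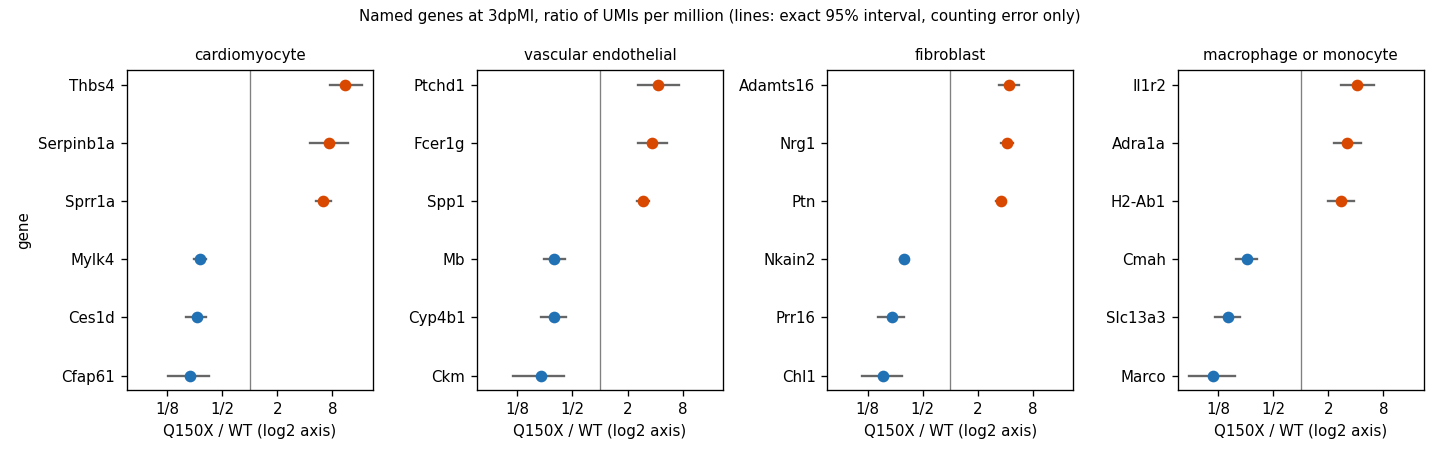
Ratio of CPM, Q150X over WT (log2 axis), at 3dpMI for the 6 genes picked by the fixed rule in each of 4 classes (y axis), with lines giving exact 95% intervals. Cardiomyocyte ratios run from 0.223 for Cfap61 to 11.1 for Thbs4.

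The libraries taken after infarction were compared with homeostasis within each genotype, with ratios of 3dpMI over homeostasis. The labels name no sham-operated group, and the 3dpMI libraries differed from the homeostasis libraries in depth and mitochondrial share. Surgery and library preparation can therefore not be told apart from infarction in these ratios. In cardiomyocyte-like nuclei stress and fetal genes were higher at 3dpMI in both genotypes. They were up in all 18 measured members in WT, with a median log2 ratio of 1.66 (1.42 to 1.84), and in all 19 in Q150X, with a median of 2.59 (2.26 to 2.87). Nppa, the gene of atrial natriuretic peptide, was at 22.2 (11.6 to 48.9) in WT and 74.4 (33.9 to 204) in Q150X. Sprr1a had 0 UMIs at homeostasis in WT and was at least 19.0-fold higher at 3dpMI, against a floor of 3 counts, with a lower 95% bound of 15.3. In Q150X it also had 0 UMIs at homeostasis, and the lower 95% bound was 96.6. Fatty acid oxidation genes had a median of 0.35 (0.23 to 0.50) in WT, which came to -0.021 relative to the median of all genes, and of -0.39 (-0.53 to -0.33) in Q150X, where 20 of 25 were lower. Ppargc1a was at 0.305 (0.296 to 0.315) in WT and 0.141 (0.134 to 0.149) in Q150X. Oxidative phosphorylation genes had a median of 0.57 (0.46 to 0.67) in WT and -0.23 (-0.30 to -0.11) in Q150X, and hypoxia and glycolysis genes of 0.78 (0.53 to 0.995) and 0.61 (0.37 to 0.79). The median of all genes in this class was 0.37 in WT and 0.18 in Q150X. Cluster 6 held 67.1% of WT cardiomyocytes at homeostasis and 15.4% at 3dpMI, and the stress median within it was 1.252. Within cluster 3 the stress median was 1.13 in WT and 0.33 (0.062 to 0.81) in Q150X, and in Q150X the medians of fatty acid oxidation, 0.17 (-0.071 to 0.24), and oxidative phosphorylation, 0.075 (-0.037 to 0.27), were not lower there. The hypoxia median within cluster 3 was 0.47 in WT and 0.22 (-0.007 to 0.44) in Q150X, and within clusters 3 and 6 in WT fatty acid oxidation had medians of 0.57 and 0.46 and oxidative phosphorylation of 0.69 and 0.94.

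By the fixed rule in WT cardiomyocytes, the synaptic adhesion gene Nrxn3 was 52.0-fold (28.2 to 109) higher, with 36.9-fold (23.5 to 61.7) in Q150X, and the WT value came to 24.7 with nuclei weighted equally. Astn1, a neuronal adhesion gene with 1 UMI at homeostasis in WT, was 115-fold (20.4 to 4544) higher, with 30.1-fold (9.99 to 148) in Q150X. On the low side were the long noncoding RNA Lncbate10 at 0.0256 (0.0100 to 0.0544), Dct, a gene of melanin synthesis, at 0.0905 (0.0535 to 0.146), and Fgf12 at 0.138 (0.0745 to 0.243), with Q150X ratios of 0.00564 (0.000142 to 0.0319), 0.0783 (0.0329 to 0.161) and 0.310 (0.0540 to 1.24). Fgf12 in WT came to 0.420 without doublet removal and 0.0593 with nuclei weighted equally.

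In fibroblast-like nuclei matrix and activation genes were higher at 3dpMI in both genotypes. Activated fibroblast genes were up in 17 of 18 members in WT with a median of 3.23, whose range from the bounds of its members was 2.28 to 4.65, and in 16 of 18 in Q150X with a median of 4.14 (3.65 to 4.70). Matrix genes had medians of 1.56 (1.47 to 1.76) and 1.55 (1.46 to 1.63). Tnc, the gene of tenascin C, was 239-fold (116 to 593) higher in WT and 69.1-fold (54.3 to 89.3) higher in Q150X. Kif26b, a kinesin family gene, was 1007-fold (279 to 8313) higher in WT, on 2 UMIs at homeostasis, and 453-fold (275 to 810) higher in Q150X. Cthrc1, a marker of reparative fibroblasts, had 0 UMIs at homeostasis in WT and was at least 42.3-fold higher against the same floor, with a lower 95% bound of 34.3, and 18.3-fold with the 1000-UMI minimum. In Q150X it also had 0 UMIs at homeostasis, with a lower 95% bound of 110. Proliferation genes were higher in all 20 measured members in WT and all 20 in Q150X, with medians of 3.02 (2.70 to 3.17) and 4.58 (4.21 to 4.92), the first 1.96 with the 1000-UMI minimum and 4.17 with libraries clustered separately. Resting fibroblast genes were lower in 13 of 14 members in WT and 13 of 14 in Q150X, with medians of -0.71 (-0.82 to -0.56) and -1.39 (-1.46 to -1.32). The lowest genes in WT were Rasef at 0.103 (0.0612 to 0.171), Col4a3, a basement membrane collagen, at 0.105 (0.0878 to 0.126), and Efhd1 at 0.119 (0.0802 to 0.176), with Q150X ratios of 0.0901, 0.0341 and 0.158. Cluster 0 held 91.8% of WT and 92.7% of Q150X fibroblasts at homeostasis but 15% and 4.38% at 3dpMI, and within it alone the activated median was -0.062 in WT and 0.78 in Q150X, the matrix median 0.45 and 0.63, and the resting median 0.18 (0.012 to 0.27) and 0.054 (-0.11 to 0.28), not lower as in the class. The proliferation median within cluster 0 was 0.098 (-0.26 to 1.68) in Q150X, and within cluster 18 the matrix median was 0.38 and the resting median 0.094 in WT.

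In vascular endothelial-like nuclei capillary identity genes were lower at 3dpMI in both genotypes, with medians of -0.37 (-0.52 to -0.22) in WT and -0.37 (-0.65 to -0.21) in Q150X, or -0.19 (-0.36 to -0.067) and -0.23 (-0.39 to 0.020) within cluster 1 alone. Arterial and Notch genes had medians of 0.31 (0.16 to 0.57) and 0.82 (0.59 to 1.15), but -0.033 (-0.31 to 0.21) and 0.16 (-0.047 to 0.50) within cluster 1 alone, and the gap junction gene Gja5 was at 4.12 (2.18 to 8.78) in Q150X. Adhesion and activation genes were up in 8 of 8 members in WT, with a median of 1.07 (0.70 to 1.69), and in 6 of 8 in Q150X, with a median of 0.86 (0.51 to 1.53) that turned to -0.52 with a minimum of 1000 UMIs per nucleus and was 0.29 (-0.086 to 1.58) within cluster 1. The kinase genes Camk1d and Cdk8 were 33.4-fold (25.9 to 43.8) and 24.3-fold (19.6 to 30.6) higher in WT, and 10.3-fold (8.75 to 12.3) and 7.75-fold (6.54 to 9.24) higher in Q150X. Both were higher in every other class measured too. Over all nuclei they were 9.42-fold and 7.92-fold higher in WT, and 6.565-fold and 4.34-fold higher in Q150X. Lyz2, the lysozyme gene of macrophages, was 87.3-fold (15.6 to 3455) higher in WT, on 1 UMI at homeostasis and 460 at 3dpMI. In Q150X it was 15.9-fold (8.01 to 37.1) higher. The lowest genes in WT were Lrrc36 at 0.225 (0.131 to 0.390), Robo2, a guidance receptor, at 0.246 (0.186 to 0.327), and Dlg2, a scaffold protein, at 0.357 (0.318 to 0.402), with Q150X ratios of 0.576, 0.307 and 0.359. Cluster 1 held 93.5% of the class in WT at homeostasis and 69.9% at 3dpMI. List medians of macrophages against homeostasis are not given, because the WT homeostasis library had 73 such nuclei.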

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

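In this part the tests of a lower cardiomyocyte yield alone and its alternatives, of breakage during isolation and of Gphn across classes were chosen after the results were seen, as were the values within single clusters and the share with doublets kept.

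The Q150X over WT difference pointed in opposite directions at homeostasis and at 3dpMI in 3 results, and with 1 library per group the difference between the 2 times was not tested. The median log2 ratio of fatty acid oxidation genes in cardiomyocytes was 0.426 at homeostasis and -0.459 at 3dpMI. The share ratio of endocardial nuclei was 1.70 and 0.7015, and that of pericytes 2.23 and 0.4907. These are results in which the interval, and for lists the wider range from the bounds of the members, lay on opposite sides of no difference, and for lists also the percentile among random lists (in the outer 2.5% at each end) and the sign relative to all genes, a criterion tightened after seeing the data. VEGF ligands and receptors in cardiomyocytes (1.13 and -0.44) and resting fibroblast genes (0.24 and -0.29) also pointed in opposite directions, as did oxidative phosphorylation genes in cardiomyocytes (0.66 and -0.080), but for each of these lists the wider range included 0 at 1 of the times. Among nuclei other than cardiomyocytes the intervals of the endocardial shares at homeostasis overlapped, at 3.655% (2.963 to 4.454) in WT and 4.493% (3.951 to 5.086) in Q150X. The pericyte ratios among such nuclei were 1.616 (1.405 to 1.858) and 0.4458 (0.3820 to 0.5202), still on opposite sides of 1. The alternative settings were not applied to the endocardial and pericyte shares.

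The lower cardiomyocyte share in Q150X was found at both times. The other classes also changed in proportion to each other, which a lower yield of cardiomyocytes alone would not bring about. Among the other nuclei the highest share ratio of 4 classes, that of macrophages, was 4.506 times the lowest, that of endothelial nuclei, at homeostasis and 4.431 times at 3dpMI. With other filters, doublet handling or clusters this came to 3.50 to 24.3 times at homeostasis and 3.0 to 5.28 at 3dpMI. These values do not bear on the share of cardiomyocytes itself, for which a lower yield was not tested and stays open. Loss as doublets or as unnamed nuclei is argued against by the share ratio with both added back, 0.3765 at homeostasis and 0.4090 at 3dpMI. Breakage of cardiomyocytes during isolation would leave more of their RNA free in the suspension. At homeostasis the cardiomyocyte markers had Q150X over WT ratios of 1.413 (1.362 to 1.465) in fibroblast, 1.720 (1.586 to 1.868) in pericyte, 1.526 (1.346 to 1.735) in macrophage and 2.624 (2.469 to 2.789) in endothelial nuclei, as breakage would give, but 1.025 (0.9079 to 1.160) in endocardial nuclei, an interval that includes 1. At 3dpMI the ratios were below 1 in these 5 classes, with 0.4479 (0.4362 to 0.4600) in fibroblast and 0.3865 (0.3590 to 0.4158) in pericyte nuclei, above the cardiomyocyte share ratio of 0.368, and 0.3380 (0.3028 to 0.3767) in endocardial, 0.3326 (0.3219 to 0.3435) in macrophage and 0.2803 (0.2677 to 0.2934) in endothelial nuclei, under it, and the pericyte and endocardial intervals include it. At homeostasis the classes disagree, so breakage cannot be told apart from a lower number of cardiomyocytes. At 3dpMI no class showed the ratio above 1 that breakage would give. The classes lay on both sides of the share ratio, so breakage cannot be told apart from a lower number there either. An effect of the genotype also stays open, untested with 1 library per group.

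The higher stress genes and lower fatty acid oxidation genes in Q150X cardiomyocytes at 3dpMI came with a larger share of cluster 13. The stress median in fibroblasts was -0.060, so the list did not rise within those nuclei. This does not decide on free RNA of other cell types, because its amount also depends on the shares of those cells, which differed. Fatty acid oxidation genes were not tested in this way. Within cluster 13 and cluster 3 alone the stress medians were 0.476 and 0.078. The test set a lower and a higher bound relative to the class median. Both medians would lie under the lower bound with a shift in cluster shares, and over the higher bound without one. The median in cluster 13 lay between the bounds and that in cluster 3 under the lower. A shift in cluster shares can therefore not be told apart from a difference within nuclei of like state. The fatty acid oxidation medians within clusters 13 and 3 were -0.150 and -0.057, both under the lower bound in size, as a larger share of cluster 13 would give. However, clusters are made from expression, so that a difference in each nucleus also appears as a cluster share. Whether the genotype leads to more such nuclei was not tested, with 1 library per group.

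Gphn, Lars2, Cmss1, Camk1d and Cdk8 differed between libraries in many classes. Over all nuclei Gphn stood at 4901 CPM in WT homeostasis, 1804 in Q150X homeostasis, 4904 in WT 3dpMI and 5824 in Q150X 3dpMI, and Cmss1 at 1325, 2651, 16438 and 21235. The ratios of Gphn at homeostasis differed by 2.305 times between 6 classes, which argues against a property of the library that changes CPM by the same factor in every class. All were below 1, as were those of Lars2 in these classes, while those of Cmss1 were above 1. A property of the library with effects of unlike size in the classes therefore stays open. In WT 3dpMI fibroblasts the Cmss1 CPM in the deeper nuclei was 0.5587 (0.5515 to 0.5659) of that in the shallower ones. An effect of more UMIs per nucleus would make it higher. Depth also went with cluster there, with median UMIs of 1638.5 in cluster 0 and 8517.5 in cluster 16. The split by depth therefore also split the clusters, and it does not decide on an effect of depth. Reads from repeats or ribosomal RNA placed in these genes were not tested and stay open, as does the genotype.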

How the results depend on the processing

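In this part the values within single clusters and with endothelial-scoring clusters added were chosen after the results were seen. Over 206 results and 2108 alternative values, 1805 stayed within the counting interval of the main value, 283 lay outside it and 20 were reversed. A reversal was counted only where the interval of the main value left out no difference. Where it did not, a change of direction is among the 1805 or the 283. For the 18 results that answer a comparison these numbers were 150, 50 and 2. Leaving out a replicate could not be done with 1 library per group, and thinning to 500 UMIs was not run because no share of nuclei with a UMI is given. No paired analysis was possible because the labels pair no libraries. Except where a sentence says so, the cause of a change was not tested.

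With a minimum of 1000 UMIs per nucleus the cardiomyocyte share ratio at homeostasis was 0.447, the endothelial share ratio at 3dpMI 0.672 and the capillary median at homeostasis -0.77. In endothelial nuclei, 3dpMI over homeostasis, this minimum reversed adhesion (-0.52), interferon (-0.32), hypoxia (-0.027), chemokine (-1.07) and immediate early genes (-0.49) in Q150X, and interferon (-0.17) and cell death genes (-0.069) in WT. This setting leaves fewer nuclei by construction. Median endothelial depth at homeostasis was 817 UMIs in WT and 653 in Q150X.

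With libraries clustered separately the share ratios at 3dpMI were 0.403 for endothelial nuclei and 1.69 for macrophages, and the capillary median was -0.61. This setting reversed, for Q150X over WT, arterial genes at 3dpMI (-1.08), endothelial interferon genes at 3dpMI (-0.16), endothelial proliferation at homeostasis (-0.67), oxidative phosphorylation at 3dpMI (0.005) and macrophage immediate early genes at 3dpMI (0.001), and endothelial proliferation over homeostasis in WT (-0.71). At resolution 2 the share ratios at 3dpMI were 0.553 for endothelial nuclei and 1.70 for macrophages, the capillary median -0.66, and endothelial interferon genes reversed for Q150X over WT at 3dpMI (-0.004) and for infarction in Q150X (-0.054).

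Without doublet removal the endothelial share ratio at 3dpMI was 0.361, the capillary median -0.28 and the stress median 1.23. With at most 5% mitochondrial UMIs the macrophage share ratio at 3dpMI was 2.15 and the capillary medians -0.62 at homeostasis and -0.61 at 3dpMI. With the endothelial-scoring clusters added, the endothelial share ratio at 3dpMI was 0.625 and the capillary median -0.54.

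Centred on the median ratio, Vegfa in cardiomyocytes at homeostasis was 1.14, fatty acid oxidation 0.25 and the infarction stress median in WT 1.28, and infarction in WT reversed for fatty acid oxidation (-0.021) and calcium handling (-0.26), since centring subtracts the median of all genes. With totals without mitochondrial and top genes, Vegfa at homeostasis was 1.20, fatty acid oxidation 0.33, and calcium handling after infarction in WT reversed (-0.042). With nuclei weighted equally, Vegfa at 3dpMI was 1.2499, the stress medians after infarction 1.35 in WT and 2.07 in Q150X, and the activated fibroblast medians 0.79 for Q150X over WT at 3dpMI and 2.51 for infarction in WT. Without its 2 members with most UMIs the activated fibroblast median was 0.47 for Q150X over WT at 3dpMI, 2.34 for infarction in WT and 3.19 in Q150X, and with members of at least 100 UMIs it was 3.63 for infarction in WT.

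Within single clusters, for Q150X over WT at 3dpMI, the stress median was 0.078 in cluster 3 and 0.48 in cluster 13, and fatty acid oxidation -0.057 and -0.15. The activated fibroblast median was 0.045 in cluster 0, 0.29 in cluster 4, 0.54 in cluster 7 and 0.30 in cluster 16, and the recruited macrophage median 0.52 in cluster 2, 0.095 in cluster 8, 0.99 in cluster 9, 0.60 in cluster 11 and 0.39 in cluster 22. The capillary median was -0.33 in cluster 1, -0.18 in cluster 15 and -0.18 in cluster 17, and tip-cell genes reversed in cluster 1 (-0.13). At homeostasis fatty acid oxidation was 0.53 in cluster 6. For infarction the stress median in WT was 1.13 in cluster 3 and 1.252 in cluster 6, and in Q150X 0.33 in cluster 3. The activated fibroblast median reversed in WT in cluster 0 (-0.062), and was 0.40 in cluster 18 and, in Q150X, 0.78 in cluster 0. Of 106 list medians with an interval off 0 and a cluster to compare, 32 had the opposite sign in at least 1 cluster of the class and 11 in every one compared. A class mixes clusters that differ between libraries, so these values hold clusters fixed.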

Other observations

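In this part the clock genes were chosen after values of some of them were seen, and Sema3a and Fgf12 were noticed as named genes before the atrial test was set. The test on Sln, Myl7 and Bmp10 was also chosen after their counts were seen.

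Neutrophil-, dendritic- and B cell-like nuclei also took larger shares in Q150X at 3dpMI. Neutrophil-like nuclei made up 0.679% (0.512 to 0.883) in WT and 2.05% (1.74 to 2.40) in Q150X, a ratio of 3.02 (2.22 to 4.11), and none were found at homeostasis, with upper 95% bounds of 0.0894% in WT and 0.0600% in Q150X. Dendritic-like nuclei had a ratio of 1.90 (1.52 to 2.39), B cell-like nuclei of 2.56 (1.74 to 3.76) and T or NK cell-like nuclei of 1.29 (0.938 to 1.78), an interval that includes 1. Schwann- or neuron-like nuclei were at 0.469% in WT and 0.193% in Q150X at 3dpMI, and epicardial- or mesothelial-like nuclei at 0.412% and 0.293% at homeostasis. Median UMIs per nucleus over all classes were 1990.5 in WT and 2658 in Q150X at 3dpMI.

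Some lists were measured in several classes at 3dpMI, without a test of differences between classes. Immediate early and heat shock genes were lower in Q150X macrophages in 19 of 25 members, with a median of -0.19 (-0.29 to -0.046) that came to 0.001 with libraries clustered separately, and the inducible heat shock genes Hspa1b at 0.314 (0.239 to 0.412) and Hspa1a at 0.408 (0.315 to 0.527). Within clusters 2, 8, 9, 11 and 22 alone the macrophage median was -0.34, -0.32, 0.33, -0.14 and -0.010. In fibroblasts the median was 0.045 (-0.048 to 0.15), and 0.31, -0.24, 0.064 and 0.17 within clusters 0, 4, 7 and 16, with Fosb, a subunit of the AP-1 factor, at 2.53 (2.11 to 3.06). Interferon response genes had medians of 0.043 (-0.33 to 0.37) in cardiomyocytes (0.10 and -0.34 within clusters 3 and 13) and 0.093 (0.027 to 0.22) in fibroblasts, where it was 0.53, -0.019, -0.044 and 0.49 within clusters 0, 4, 7 and 16 alone. Cell death and p53 target genes had medians of -0.095 (-0.40 to 0.20) in cardiomyocytes, 0.089 (-0.10 to 0.34) in endothelial nuclei, 0.016 (-0.066 to 0.14) in fibroblasts and 0.12 (-0.009 to 0.24) in macrophages, each with an interval that includes 0. Against homeostasis they were higher in WT cardiomyocytes in 13 of 14 members, with a median of 1.26 (0.83 to 1.49) (0.83 and 0.76 within clusters 3 and 6), and had a median of 0.19 (-0.068 to 0.53) in Q150X. Chemokine genes in macrophages had a median of 0.077, with a range of -0.29 to 0.56 from the bounds of its members (0.040, 0.59, 0.18, 0.013 and 0.31 within clusters 2, 8, 9, 11 and 22), and the neutrophil attractant Cxcl5 was at 2.88 (1.35 to 7.06).

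Some genes of the circadian clock differed at 3dpMI. In Q150X over WT, Nr1d1, a clock repressor, was at 0.667 (0.517 to 0.852) in cardiomyocytes, 0.593 (0.514 to 0.685) in fibroblasts and 0.439 (0.316 to 0.599) in endothelial nuclei, and the clock activator Arntl at 1.54 (1.09 to 2.16), 1.4 (1.27 to 1.56) and 1.55 (1.11 to 2.16). Dbp, Hlf, Tef and Nr1d2 were also lower in each of these classes, with intervals below 1. In the same order of classes Dbp was at 0.675, 0.620 and 0.595 and Hlf at 0.444, 0.517 and 0.347. Other clock genes went against the rest of their arm, with Per1 at 1.80 (1.48 to 2.19), Per2 at 1.59 (1.28 to 1.97) and Npas2 at 0.686 (0.576 to 0.814) in cardiomyocytes and Bhlhe41 at 1.46 (1.26 to 1.68) in fibroblasts. A hypothesis is that hearts were taken at different times of day, which would move the Arntl arm and the Dbp arm of the clock apart. The difference between the medians of the arms in cardiomyocytes was -0.390 (-0.69 to 0.026) at homeostasis and 0.381 (0.091 to 0.645) at 3dpMI, in fibroblasts -0.14 (-0.31 to 0.21) and 0.28 (0.12 to 0.47), and in endothelial nuclei -0.53 (-1.17 to 0.077) and 1.12 (0.57 to 1.597). The bound set for the hypothesis was a size of at least 1 with the same sign in each class. Only the endothelial value at 3dpMI reached that size, and at each time the sign was the same in each class. The bound set against the hypothesis was a size under 0.5 in cardiomyocytes and fibroblasts. The fibroblast values lie under that bound with their intervals, but the fibroblast interval at 3dpMI leaves out no difference. The intervals of the cardiomyocyte values reach past the bound, so the values do not decide on the hypothesis at either time. The labels give no time of day.

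Sema3a and Fgf12 were lower in Q150X cardiomyocytes at homeostasis, and a hypothesis is that fewer atrial cardiomyocytes were in that library. The first test needed atrial genes with at least 20 UMIs, and 0 of 6 reached that at homeostasis, so it decides nothing. Atrial cardiomyocytes would also bring their abundant transcripts Sln, Myl7 and Bmp10, but these had 0 UMIs in WT cardiomyocytes, with an upper 95% bound of 1.204 CPM together, while Sema3a stood at 24.5 CPM in WT and 3.66 in Q150X and Fgf12 at 16.3 and 2.99. The other atrial genes, Myl4, Dkk3 and Nppa, had 5, 2 and 9 UMIs in WT and 6, 0 and 6 in Q150X. That Sln, Myl7 and Bmp10 are abundant in atrial nuclei was not measured here, and the test was chosen with their counts known. The values go against fewer atrial cardiomyocytes as the cause only if that abundance holds. An effect of the genotype stays open, untested with 1 library per group.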
